A study of Mus musculus with 7 samples.

How the data were processed

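Total RNA from 7 cultures of mouse splenic B cells was sequenced after ribosomal RNA depletion, 3 labelled wild type and 4 labelled cKO MED1. Per the labels' protocols, purified B cells were kept for 4 days with lipopolysaccharide (LPS, 1 µg/mL) and interleukin 4 (IL-4, 20 ng/mL), libraries were made with a stranded total RNA kit and 14 cycles of amplification, and paired reads of 150 bp were collected on a NextSeq 500. The labels do not say whether the replicates came from separate mice, so p-values measure the spread between these samples.

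The authors deposited 1 table of values per gene for the 7 libraries, a signal made of read counts that had been divided by 1 size factor per library. This follows from the values themselves: 100% of the values were whole multiples of the smallest step of their library, within a tolerance of 1e-06, so the whole reads could be recovered. Per the submitters' processing notes, STAR 2.4.0a, featureCounts, Subread 1.5.0-p3, R 3.4 and DESeq2 were used with the mouse build GRCm38 (mm10). Which of these tools made which step, and whether strand was used in counting, is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. The table lists 46959 features besides the phiX174 spike-in, whose share was at most 0.000383% of the reads and which was left out. Positions and exonic lengths were taken from the GENCODE annotation of GRCm38 by gene symbol, which placed 44864 features (95.5%).

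Recovered reads ranged from 31937372 to 61149274 per library, and every wild-type library was deeper than every cKO MED1 library. Intervals from read counts would cover counting error alone, so the spread between replicates is given as SD. Recovered reads were scaled with TMM factors (edgeR 4.0.16) to a common effective library of 48019763 reads and are called normalised reads. Genes were kept by edgeR's filterByExpr, which left 18062. The test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(normalised reads + 1), with the Benjamini-Hochberg adjusted p threshold at 0.05. Fold changes are on that log2(value + 1) scale, which understates changes of genes with few reads, and stand as cKO MED1 minus wild type. The design fixed before the data were examined named edgeR's quasi-likelihood test on counts. Because the deposited values were not counts, limma became the main test and the edgeR test on recovered reads became an added alternative, which called 5340 genes. Some fits with edgeR, and with limma under the authors' scaling, had been looked at before the limma fit with TMM factors was settled. On simulated reads for these 18062 genes, limma recovered 18.2%, 67.2% and 80.6% of 66, 67 and 67 genes changed by 0.5, 1 and 2 on the log2 scale, with 9 false calls. With so few changed genes the adjusted threshold is stricter there than in the real data. The bounds for the neuronal and muscle subtraction among high genes and for loss of Med1 in the satellite reads were rewritten after their values had been seen.

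The 30 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, on the same log2 values in place of the planned log2 CPM. Camera with a correlation estimated per list and fry were run beside it. A list of 25 simulated members lowered by 0.5 was called by camera at adjusted p = 5.53e-21 with 0 other lists called. The simulated genes were drawn independently of each other, whereas the estimated correlation was 0.73 in the cell cycle list. The simulation therefore does not measure false list calls among correlated genes. Shares of reads were compared with a two-sided exact permutation test over all 35 assignments of the 7 libraries, whose smallest p is 0.0286, and adjusted over 11 comparisons.

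Named genes follow a rule fixed before the data were examined. It takes Med1, the 8 IgH constant genes, Igkc and Jchain whatever their result, and the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 5 in the higher group and no overlap between groups. Ig and T cell receptor segments, predicted genes, clones, pseudogenes, Y-linked genes and Xist were excepted. From each list it takes up to 4 members with the smallest adjusted p. Some genes that the rule takes are not reported here. Genes named outside the rule were chosen after their values were seen.

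Alternatives chosen before the data were examined were RLE factors, total reads, scaling without Ig genes, no filter, a filter of CPM 1 in 3 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, a threshold of 0.01, the replicate number as a block, 1 surrogate variable (sva 3.50.0) and each library left out. Alternatives added after seeing the data were edgeR's test, the authors' size factors, a pseudocount of 5, a fit without cKO MED1 replicates 3 and 4, sex as a covariate, and subtraction of a background per kb of exon. The background was the level of olfactory and vomeronasal receptor genes (1819 genes) or the median of 38 neuronal and muscle genes. Genes left above 0 in fewer than 3 libraries after subtraction were not fitted, a filter set after a first subtraction fit had returned variances of 0. Near-identical copies of transcripts were sought with BLAST 2.17.0 at 95% identity over 80% of the length. Pairs of libraries within a group differed far beyond sampling noise (chi-square per degree of freedom at least 53.8), so none was treated as a duplicate.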

Results

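RNA was measured in mouse splenic B cells after 4 days of culture with LPS, a bacterial activator of B cells, and IL-4, a cytokine that directs switching towards IgG1 and IgE. Wild-type cells (n = 3) were set against cells labelled cKO MED1 (n = 4), named for Med1, a subunit of the Mediator complex, which links enhancer-bound factors to RNA polymerase II. Recovered reads numbered 61149274, 55453522 and 54736580 in wild-type replicates 1 to 3 and 33924364, 49603193, 41699903 and 31937372 in cKO MED1 replicates 1 to 4. The series title places the question at the immunoglobulin heavy chain (IgH) locus, asking whether Med1 is needed for the expression and hypermutation of IgH genes.

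Med1 itself was lower in all 4 cKO MED1 libraries. Its normalised reads were 4756, 4173 and 4210.1 in wild-type replicates 1 to 3 and 2585, 2172, 2249.5 and 2436 in cKO MED1 replicates 1 to 4. The means were 4379.5 ± 326 (SD, n = 3) and 2360.6 ± 186 (SD, n = 4), so that 53.9% of the wild-type level remained, and the log2 fold change was -0.89 (SE 0.09, limma adjusted p = 0.000174). Med1 (ENSMUSG00000018160.15) lies on chromosome 11 from 98152154 to 98193293 in GRCm38, and values for the whole gene do not separate a targeted exon from the rest of the transcript.

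Of the 8 IgH constant genes, 6 fell in cKO MED1, and the same 6 when adjusted over the list alone. The largest fall was that of Ighg3, which encodes the IgG3 heavy chain, from 4588 ± 3123 (SD, n = 3) to 752 ± 233 (SD, n = 4) normalised reads, a log2 fold change of -2.46 (SE 0.35, limma adjusted p = 0.00126). Wild-type replicate 3, at 8184 reads, held much of that group's spread. The genes of the isotypes that IL-4 directs fell as well. Counts for a whole gene do not separate germline transcripts, made before switching, from heavy chain transcripts of switched cells. Ighe went from 5738 ± 332 to 2646 ± 608 reads (log2 fold change -1.14, SE 0.15, limma adjusted p = 0.000732), and Ighg1 from 48491 ± 2592 to 29746 ± 5333 (log2 fold change -0.72, SE 0.15, limma adjusted p = 0.00791). Ighg2b fell by 1.19, Ighd by 0.94 and Igha by 0.58 on the log2 scale (limma adjusted p = 0.00347, 0.00268 and 0.0259). Ighm, the most abundant of the 8, stood at 744760.0 ± 215730.0 reads in wild type and 797830.0 ± 96615 in cKO MED1, and its log2 fold change of 0.13 (SE 0.34) was within the replicate spread (limma adjusted p = 0.79). Ighg2c did not pass either (limma adjusted p = 0.168), with 108 and 105 reads in cKO MED1 replicates 1 and 2 against 506 and 549 in replicates 3 and 4. It was called lower in 5 alternatives, among them the replicate block (-1.44, limma adjusted p = 0.00978) and the fit without cKO MED1 replicates 3 and 4 (-2.19, limma adjusted p = 0.00228). No wild-type library shares the number of cKO MED1 replicate 4, so the block leaves that library without weight in the genotype effect. Without that library and without a block the log2 fold change was also -1.44 (limma adjusted p = 0.0682). With sex as a covariate the log2 fold change of Ighg2c was 0.05. The genes lie on chromosome 12 between 113254830 and 113422730. The strain of the mice is not given in the sources used here. A sequence difference between strains at this locus could also change which reads are counted, and this was not tested. As a list the IgH constant genes had a median log2 fold change of -0.99 (camera adjusted p = 0.00193), which was lost when the correlation was estimated (adjusted p = 0.648 with an estimated correlation). By limma, 2 of the 8 passed with sex of the library as a covariate (Ighd and Ighe) and 2 with 1 surrogate variable (Ighg2b and Ighg2c). With the covariate the log2 fold changes that no longer passed were -2.064 for Ighg3, -0.847 for Ighg1, -0.872 for Ighg2b and -0.535 for Igha. With the surrogate variable they were -2.486 for Ighg3, -0.406 for Ighg1, -0.874 for Ighd, -0.808 for Ighe and -0.8 for Igha. The Igha call also ended without wild-type replicate 1 (-0.488, limma adjusted p = 0.116) and with the filter of CPM 1 in 3 libraries (-0.468, limma adjusted p = 0.0745).

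The light chain constant genes gave no call. 0 of 5 passed limma's test, 0 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2, with a list median of 0.11 (camera adjusted p = 0.816), and Igkc, the kappa constant gene on chromosome 6, held 237790.0 ± 52638 reads in wild type and 242660.0 ± 34723 in cKO MED1 (log2 fold change 0.04, SE 0.23). Jchain, which joins IgM and IgA into polymers, fell from 45865 ± 14611 to 16045 ± 7788 reads (log2 fold change -1.58, SE 0.29, limma adjusted p = 0.00455). With sex as a covariate Jchain did not pass (-0.69, limma adjusted p = 0.204), nor with 1 surrogate variable (-1.77, limma adjusted p = 0.1).

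**Figure D1:**
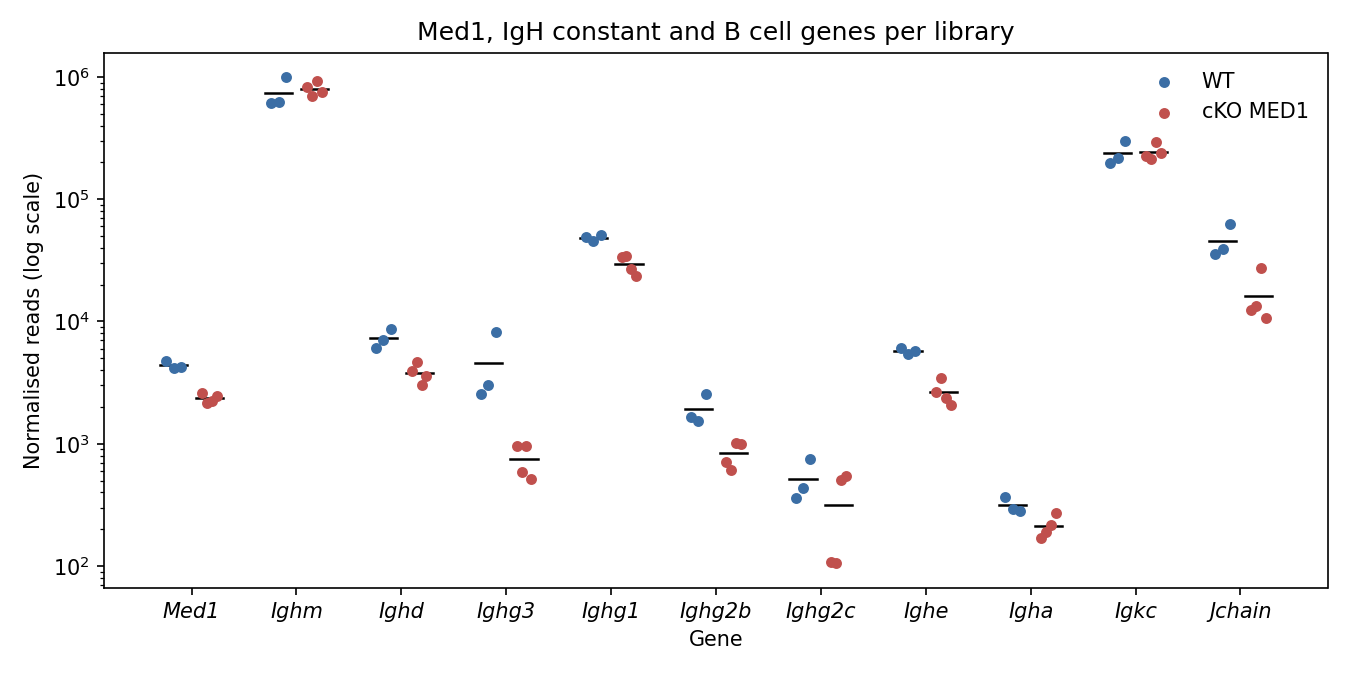
Normalised reads (log axis) of Med1, the 8 IgH constant genes, Igkc and Jchain; each point is 1 library (3 wild type, 4 cKO MED1) and each line a group mean. Med1 and 6 of the IgH constant genes lie lower in all 4 cKO MED1 libraries than in any wild-type library, while Ighm and Igkc overlap.

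Across the genome, 5065 of 18062 tested genes passed limma's adjusted p of 0.05, 2419 higher and 2646 lower in cKO MED1. Most lower calls were small: 1432 genes rose and 180 fell by a fold of 2 or more. Groups did not overlap in 4787 of the called genes, and in 39.1% of all tested genes where chance gives 5.71%. The first principal component of the log2 values held 71.5% of the variance. It placed the 7 libraries in the same order as the reads of silent neuronal and muscle genes given below. The lack of overlap can therefore follow those reads and cannot be assigned to genotype alone. By the rule for named genes the largest rises were those of BC018473 (log2 fold change 6.97), Rprl3 (6.12), one of several near-identical genes of RNase P RNA that can share reads, St6galnac2, a sialyltransferase (4.59), Cygb, cytoglobin (3.85), Lipc, hepatic lipase (3.52), the cytokine gene Il10 (2.89), Asph (2.37), the immune checkpoint receptor gene Lag3 (2.12), Dapk2 (1.69) and mt-Tq, a mitochondrial tRNA (1.64). Il10 went from 198 ± 126 (SD, n = 3) to 1372 ± 505 (SD, n = 4) reads, and Lag3 from 118 ± 49.3 to 503 ± 137. The largest falls were those of Ly6c2, a surface antigen gene (-5.02), Slfn1 (-2.72), Parm1 (-2.71), Ighg3, Ms4a4c (-2.40), Map7 (-2.39), Slfn8 (-2.32), the phosphodiesterase gene Pde2a (-2.27), the RNA-binding protein gene Igf2bp3 (-2.20) and Tacc2 (-2.17). Ly6c2 dropped from 1548 ± 940 to 47.2 ± 24.9 reads.

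Sex went largely with genotype: reads of the Y-linked gene Ddx3y were at 4496 to 4895 in all 3 wild-type libraries and at 4469.9 in cKO MED1 replicate 3, against at most 4.07 in cKO MED1 replicates 1, 2 and 4, and Xist, the X-inactivation RNA, was at 40414, 36381 and 41073 reads in those 3. With sex as a covariate, 228 genes were called, a fit in which the genotype effect rests on the 1 male cKO MED1 library, and without wild-type replicate 1 the count was 1362. The balance of directions depended on scaling, as 47.8% of the calls were higher here, 37.3% with the authors' size factors and 31.8% with total reads, which moved the median log2 fold change of all genes from 0.04 to -0.10 and -0.20.

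9 of the 30 gene lists were called by camera, all of them lower, and none was called with a correlation estimated per list, where 1 list reached an unadjusted p under 0.05. Direction went with expression level. Of the 6021 tested genes with the highest means, limma called 1673 lower and 337 higher, against 56 and 1298 of the 6021 with the lowest. The counts of lower members given below stand beside these shares, and camera's test does not allow for level. The list of cell cycle genes had the smallest camera p. 28 of its 35 members were lower and 0 higher, 29 adjusted over the list alone, with a median log2 fold change of -0.49 (camera adjusted p = 1.03e-08; adjusted p = 0.666 with an estimated correlation). The mean of this list per library, relative to wild type, was 0.187, -0.105 and -0.082 in wild-type replicates 1 to 3, -0.386, -0.361 and -0.351 in cKO MED1 replicates 1 to 3, and -0.716 in replicate 4. The replication helicase genes Mcm5 (-0.82), Mcm2 (-0.81) and Mcm3 (-0.73) led it together with Myc (-0.71), whose product drives growth and division. Interferon response genes fell in 19 of 30 cases, 27 adjusted over the list alone, with a median of -0.83 (camera adjusted p = 4.87e-08; adjusted p = 0.666 with an estimated correlation). Rtp4 (-1.48), the antiviral tether gene Bst2 (-1.13), Isg15 (-0.94) and the GTPase gene Gbp2 (-0.85) were among them. The mean of this list per library, relative to wild type, ranged from -0.35 in cKO MED1 replicate 1 to -1.24 in replicate 2. Of 24 genes of cholesterol and fatty acid synthesis, 10 fell, 14 adjusted over the list alone, and 0 rose (median -0.27, camera adjusted p = 8.15e-06; adjusted p = 0.666 with an estimated correlation). They included Idi1 (-0.60) of the cholesterol pathway and the fatty acid enzyme genes Scd1 (-0.55) and Acaca (-0.46). With sex as a covariate, limma called 0 members of these 3 lists, whose medians were then -0.36, -0.72 and -0.28, and 14, 18 and 7 members at an unadjusted p under 0.05.

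Genes of the class switching and hypermutation machinery fell in 14 of 39 cases, 21 adjusted over the list alone, and rose in 0 (median -0.24, camera adjusted p = 0.000126; adjusted p = 0.666 with an estimated correlation). The exonuclease gene Exo1 (-0.84) and the break-sensing and end-joining genes Nbn (-0.50) and Xrcc5 (-0.41) were among those that fell. Of 33 Mediator subunit genes, 12 fell and 2 rose, the same counts adjusted over the list alone (median -0.21, camera adjusted p = 0.00478; adjusted p = 0.666 with an estimated correlation). Besides Med1 these included Med9 (-0.60), while Med12l (0.99) and Med13l (0.44) rose. Super-enhancer cofactors and chromatin readers fell in 8 of 26 cases, 10 adjusted over the list alone, and rose in 1 (median -0.16, camera adjusted p = 0.0194; adjusted p = 0.666 with an estimated correlation). The cohesin genes Smc1a (-0.45) and Smc3 (-0.43), Ccnh (-0.37) and the insulator protein gene Ctcf (-0.35) fell. The 1 gene that rose was the X-linked demethylase gene Kdm6a (0.63), whose rise cannot be told apart from the sex of the libraries. Without cKO MED1 replicate 3 this list's camera adjusted p was 0.0864, and without replicates 3 and 4 it was 0.17.

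Mature B cell identity genes fell in 13 of 28 cases and rose in 2, unchanged in number when adjusted over the list alone (median -0.16, camera adjusted p = 0.0253; adjusted p = 0.666 with an estimated correlation). Cd79a, a signalling chain of the B cell receptor, fell from 14110.0 ± 1026 (SD, n = 3) to 7672 ± 728 (SD, n = 4) reads (log2 fold change -0.88, SE 0.10, limma adjusted p = 0.000378). The surface antigen gene Ms4a1 (-0.66) and the transcription factor genes Irf8 (-0.50) and Bach2 (-0.47) fell as well. This list's camera adjusted p was 0.0719 without cKO MED1 replicate 3, 0.0512 without replicate 4 and 0.194 without both. Nuclear-encoded genes of oxidative phosphorylation fell in 8 of 29 cases and rose in 1, also adjusted over the list alone (median -0.16, camera adjusted p = 0.00968; adjusted p = 0.666 with an estimated correlation), among them Ndufv1 (-0.61), Uqcrc1 (-0.50), Cycs (-0.43) and Sdhb (-0.39). The mean of this list per library, relative to wild type, was -0.32 and -0.26 in cKO MED1 replicates 1 and 4, but -0.053 and 0.004 in replicates 2 and 3, within the wild-type range of -0.096 to 0.086. The camera adjusted p of this list was 0.0855 without cKO MED1 replicate 1 and 0.64 with sex as a covariate.

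**Figure D2:**
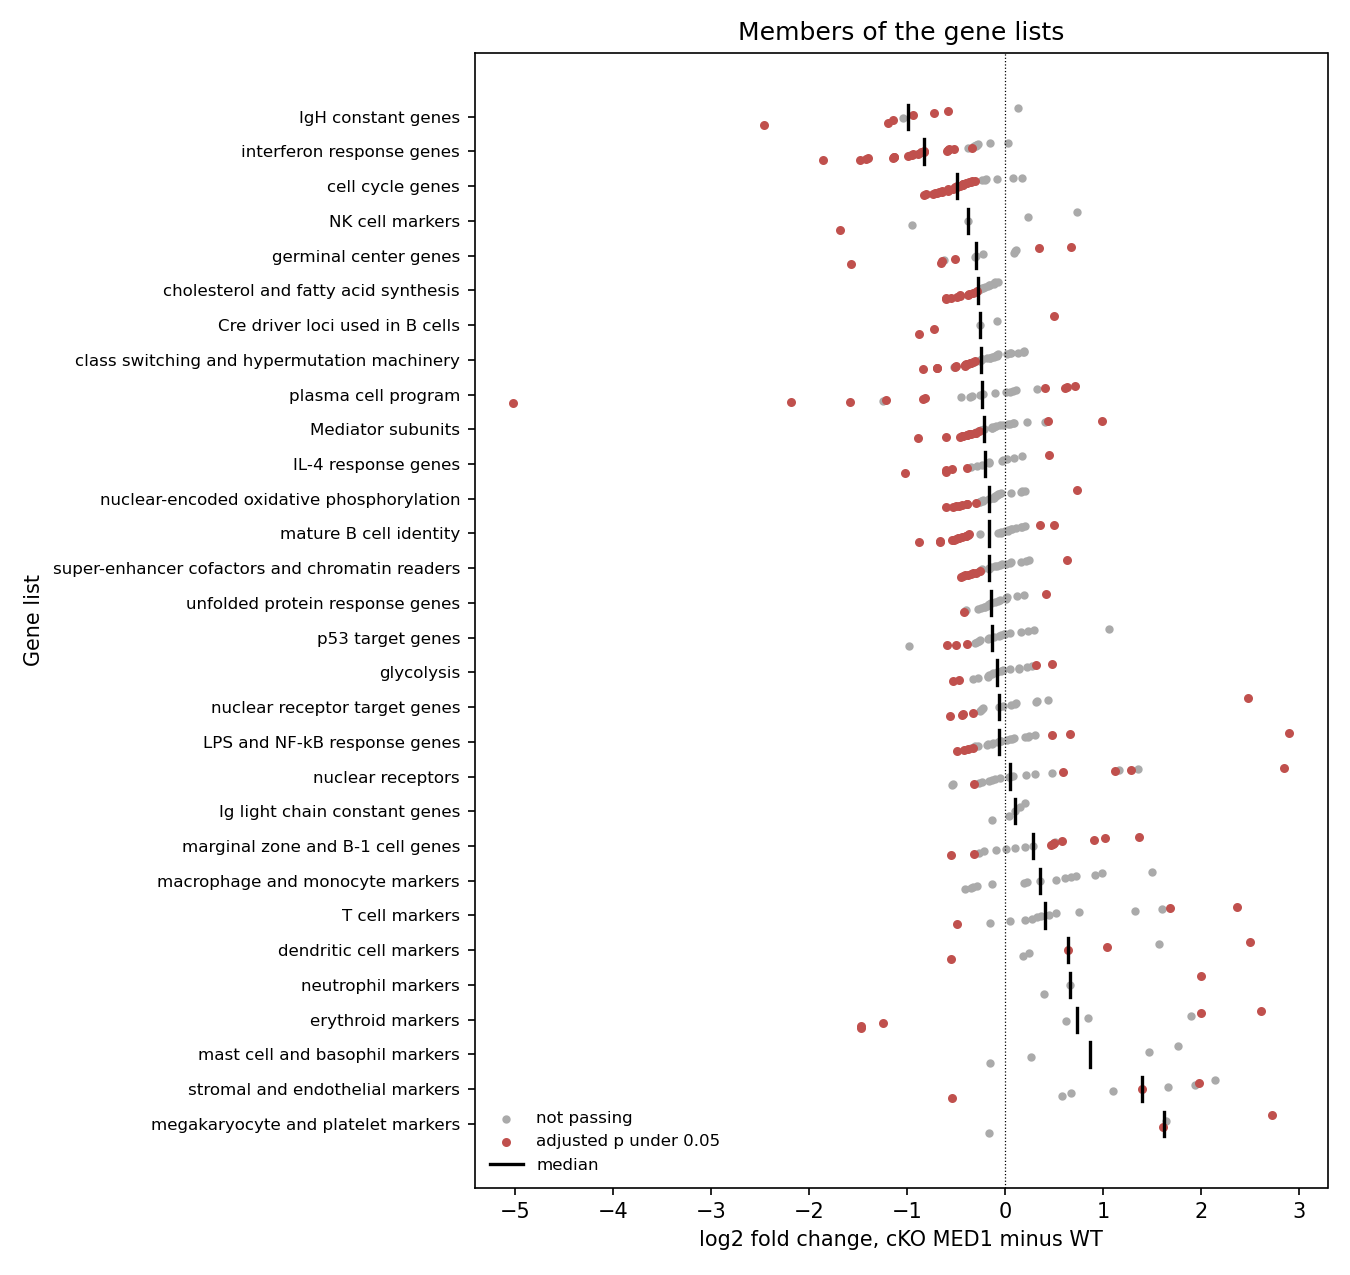
log2 fold change (cKO MED1 minus wild type) of every measured member of the 30 gene lists, ordered by list median; red points passed limma's adjusted p of 0.05, grey points did not, and black bars are medians. The medians of the IgH constant, interferon and cell cycle lists are -0.99, -0.83 and -0.49.

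Other B cell programs were mixed. In the plasma cell list, which camera did not call (adjusted p = 0.0902), 4 of 22 members rose and 6 fell, 4 and 9 adjusted over the list alone. Ly6c2 (-5.02), Ly6c1 (-2.18), Jchain and the secretory pathway gene Txndc5 (-0.84) were among those that fell. The 4 that rose were Prdm1 (0.71), Cacna1s (0.63), Derl3 (0.61) and Irf4 (0.41). Marginal zone and B-1 cell genes rose in 7 of 17 cases and fell in 2, with 8 and 2 adjusted over the list alone (median 0.28, camera adjusted p = 0.0934). Myof (1.37), the tetraspanin gene Cd9 (1.02), the Fc receptor-like gene Fcrl5 (0.90) and the lipid-presenting gene Cd1d1 (0.58) rose. Of 13 germinal center genes, Nuggc (-1.57), Bcl6 (-0.65), Gpr183 (-0.65) and Plxnb2 (-0.51) fell and S1pr2 (0.67) and Cxcr4 (0.35) rose, the same counts adjusted over the list alone (camera adjusted p = 0.216). IL-4 response genes fell in 5 of 16 cases and rose in 1, also adjusted over the list alone (median -0.20, camera adjusted p = 0.063). The chemokine gene Ccl22 (-1.02), the feedback inhibitor gene Socs1 (-0.61) and the receptor gene Il4ra (-0.60) fell, and Jak3 (0.45) rose, a call that ended in 10 alternatives and with overlap between the groups. LPS and NF-kB response genes went both ways, 3 up and 4 down of 26, the same adjusted over the list alone, with a median of -0.06, a mean of 0.06 and camera adjusted p = 0.518. Il10 and the inhibitor gene Nfkbia (0.48) rose, and the activation marker Cd83 (-0.49) and Cd180 (-0.42) fell.

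Among general programs, p53 target genes fell in 3 of 20 cases, the same adjusted over the list alone (camera adjusted p = 0.0976), namely Sesn1 (-0.59), Aen (-0.50) and Bax (-0.39). In the unfolded protein response list of 22, Ddit3 (0.42) rose and Canx (-0.42) fell, 1 and 0 adjusted over the list alone (camera adjusted p = 0.121). In the glycolysis list of 19, Ldha (-0.53) and Eno1 (-0.47) fell and Aldoc (0.48) and Pfkm (0.32) rose, 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.413). The Pfkm call ended in 16 alternatives and the Aldoc call in 11, and the groups overlapped for Aldoc. Nuclear receptors rose in 4 of 21 cases and fell in 1, and their target genes rose in 1 of 17 and fell in 4, which adjusted over the list alone gave 4 and 1 and 1 and 5 (camera adjusted p = 0.518 and 0.278). Ppard (0.60) and Esr1 (1.12) were among the receptors that rose. The list of loci used for Cre drivers in B cells held Cd79a and Ighg1, which fell, and Cr2 (0.50), which rose, of 5 members, the same adjusted over the list alone (camera adjusted p = 0.14).

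Markers of other cell types were mostly at low levels, and none of their lists was called by camera. The medians were 0.41 for T cells (adjusted p = 0.123), -0.38 for NK cells (0.518), 0.35 for macrophages and monocytes (0.518), 0.66 for neutrophils (0.14), 0.65 for dendritic cells (0.121) and 0.87 for mast cells and basophils (0.278). They were 1.62 for megakaryocytes and platelets (0.121), 1.40 for stromal and endothelial cells (0.121) and 0.74 for erythroid cells (0.902), a list whose test pointed lower. Relative to wild type, the stromal list's mean was 0.32, 0.96, 1.38 and 2.20 in cKO MED1 replicates 1 to 4. The mast cell list's was -0.38, 0.47, 1.35 and 1.90. Both rose in the order of the silent-gene reads given below, whereas the NK cell list, at -0.96, -0.65, 0.30 and -0.32, did not. Lat (1.68), Itga2b (1.61) and Batf3 (1.04) rose, and Tfrc, the transferrin receptor gene, fell from 11440.0 ± 3096 to 4793 ± 931 reads (log2 fold change -1.24, SE 0.18, limma adjusted p = 0.00143). Adjusted over the list alone, called members numbered 3 of 14 for T cells, 1 of 5 for NK cells, 0 of 15 for macrophages and monocytes, 2 of 3 for neutrophils, 5 of 7 for dendritic cells, 6 of 8 for erythroid cells, 2 of 4 for megakaryocytes, 0 of 4 for mast cells and 5 of 9 for stromal cells. Over all genes tested these were 3, 1, 0, 1, 4, 5, 2, 0 and 3. At an unadjusted p under 0.05 limma gave 4 macrophage and 2 mast cell markers, and after adjustment edgeR called 0 and 2 and DESeq2 0 and 1.

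Reads of genes silent in B cells moved with the groups too. Olfactory and vomeronasal receptor genes held 0.117, 0.245 and 0.198 normalised reads per kb in wild-type replicates 1 to 3 and 0.24, 0.335, 0.612 and 1.04 in cKO MED1 replicates 1 to 4. Neuronal and muscle genes, a list set after seeing the data, had medians of 0.237, 1.02 and 0.965 reads per kb and of 1.27, 1.59, 3.55 and 6.38 in the same order. With that level subtracted, 1286 genes were higher and 2624 lower, against 2419 and 2646 before, and 6 lists were called: the Mediator, super-enhancer cofactor, mature B cell and oxidative phosphorylation lists were not, and the marginal zone list was.

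**Figure D3:**
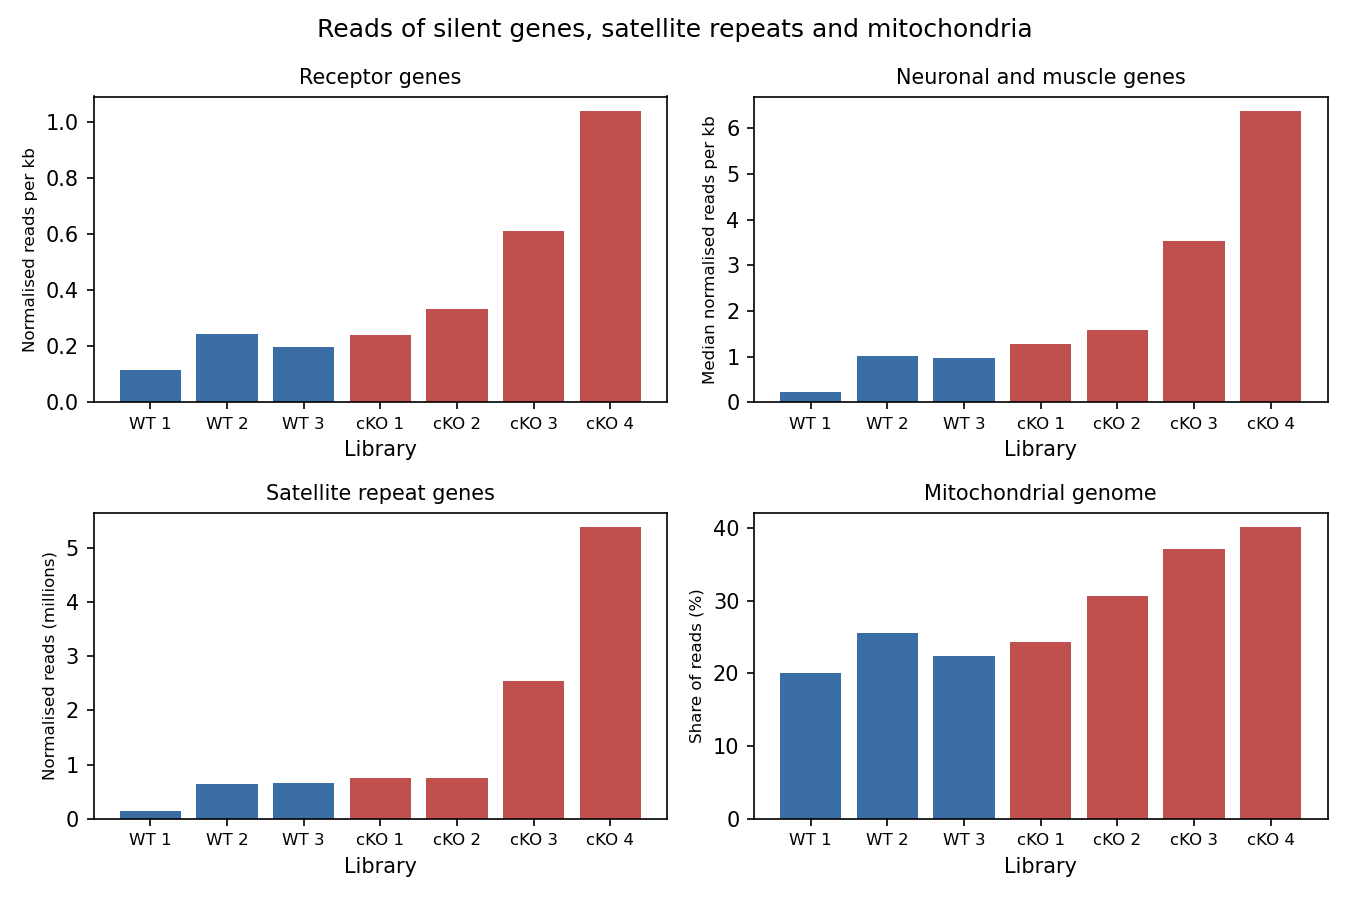
Bars give, for each of the 7 libraries, the normalised reads per kb of silent receptor genes, the median normalised reads per kb of silent neuronal and muscle genes, the normalised reads of satellite repeat genes and the share (%) of reads from the mitochondrial genome. cKO MED1 replicates 3 and 4 are highest in all 4 panels.

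Immunoglobulin genes took 3.28% ± 0.85 of all recovered reads in wild type (SD, n = 3) and 2.78% ± 0.37 in cKO MED1 (SD, n = 4), a difference of -0.497 percentage points that was within the replicate spread (exact permutation p = 0.4, adjusted 0.44). It was -0.005 without wild-type replicate 3, and -0.057 with mitochondrial and small RNA left out of the total. The IgH constant genes together, which are mostly Ighm, took 1.86% ± 0.51 and 1.62% ± 0.24 (exact p = 0.543). V segments of the heavy chain took 0.359% ± 0.107 and 0.274% ± 0.0393 (exact p = 0.2), and kappa V segments 0.374% ± 0.096 and 0.297% ± 0.0434 (exact p = 0.2). The kappa constant gene took 0.544% ± 0.119 and 0.469% ± 0.0549 (exact p = 0.343), and lambda genes 0.115% ± 0.0195 and 0.098% ± 0.0171 (exact p = 0.314). Transcripts of the mitochondrial genome, nearly all of them its ribosomal RNAs, took 22.7% ± 2.8 and 33.1% ± 7.0 (exact p = 0.0857, adjusted 0.314), with 24.4, 30.7, 37.2 and 40.2% in cKO MED1 replicates 1 to 4. Replication-dependent histone genes took 0.941% ± 0.13 and 0.584% ± 0.194 (exact p = 0.0571, adjusted 0.314), and ribosomal protein genes 6.84% ± 0.36 and 6.05% ± 1.06 (exact p = 0.314). None of the 11 shares passed after adjustment, in a design whose smallest unadjusted p is 0.0286.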

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

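The tests in this part were chosen after the data had been seen. The bounds for the receptor subtraction and for the other ribosomal protein genes were written before those 2 tests were run.

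Of 153 sets of 4 cKO MED1 libraries, 9 had 1 library far from the other 3 by Dixon's criterion, where chance flags about 1 in 20. Jchain was at 27610 normalised reads in replicate 3 against a median of 12415 in the others, and Gzmb at 26.34 in replicate 3 against 9.15. Plxnb2 was at 1955 and Acaca at 4195 in replicate 1, against 1487 and 3657. Ctsb was at 5567 in replicate 2 against 4956. Replicate 4 stood low for Mcm2 (2108 against 3046), Mcm3 (4279 against 6043), Canx (19030 against 23185) and Ndufv1 (1118 against 1401).

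Reads of silent genes and of 13 satellite repeat genes were highest in cKO MED1 replicates 3 and 4, and 95.9% of the calls in the third of genes with the lowest means were higher. Subtracting the receptor level ended 7.1% of the higher calls among these low genes and 0.6% among the third with the highest means, below the bound of 10% set before that test was run against a DNA-like background, but that bound took receptor genes for the whole background, and in cKO MED1 replicate 4 neuronal and muscle genes ran at 6.38 reads per kb against 1.04. Subtracting the neuronal and muscle level, a list drawn up after the first result and after some of its genes had been seen, ended 64.0% of the higher calls among low genes (median log2 1.95 to 1.53, SE 0.56 to 0.68) and 19.6% among high genes (0.45 to 0.44, SE 0.11 to 0.11). A DNA-like background may therefore account for many higher calls of low genes. Among high genes, 271 of 337 higher calls passed after the second subtraction. The 19.6% that ended lay above the bound of 10%, and the bound for that test was rewritten after its value had been seen. High genes had means of at least 932 reads, and the level subtracted was at most 6.38 reads per kb. Few of their calls could end at that level, so the subtractions decide little about them. Loss of Med1 stays open for the satellite reads, because all 4 cKO MED1 libraries lay above all 3 wild-type libraries, the lowest of them at 1.14 times the highest wild-type library, while the wild-type libraries themselves ranged from 147723 to 657917 reads.

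Rpl29, a ribosomal protein gene named here after its value was seen, dropped by 10696 normalised reads, from 14110 to 3414, while 25 near-identical copies together gained 10452. The sum of Rpl29 and its copies differed by -0.02 on the log2 scale (SE 0.07, exact p = 0.8), so reads may have moved between copies, as a sequence difference of another mouse strain would cause. Loss of ribosomal protein transcripts in general is argued against, since the median log2 fold change of the other 80 genes was 0.04 (SD over genes 0.30). Which strain the mice carried is not given in the sources used here.

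Wild-type replicate 2 held 1241 Xist reads, against 59.2 and 11.2 in wild-type replicates 1 and 3, although its Y-linked genes were at the level of the other 2. The excess was 3.07% of the mean female cKO MED1 level, and for 7 autosomal genes nearly silent in the other wild-type libraries the median excess was 3.08% (1.07 to 4.69%). Among the 7 were the Rpl29 copies Gm13841, Gm15454 and Gm8210, and Rprl3. These can share reads with near-identical genes, so the 7 are not independent markers. A small share of reads from a female cKO MED1 library is a candidate explanation. The same 7 genes had a median excess of 0.877% in wild-type replicate 3 over replicate 1 too, without more Xist, so they do not track Xist alone. They were also chosen to be expressed in the male cKO MED1 library, which held few Xist reads. Reads from that library could give such an excess, so it does not count against reads from another library. A DNA-like background is argued against, because wild-type replicate 3 had a similar level of silent genes and 111 times fewer Xist reads. No biological explanation was tested.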

How the results depend on the processing

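The tests added after seeing the data were the edgeR test, the authors' size factors, the pseudocount of 5, both background subtractions, the fit without cKO MED1 replicates 3 and 4, and the sex covariate. Med1 kept its direction and passed limma's threshold in all 25 alternatives (log2 fold change -1.13 to -0.78, adjusted p at most 0.0148). Of the 5065 calls, 2419 higher and 2646 lower, the number fell to 241 (130 and 111) with 1 surrogate variable, 228 (109 and 119) with sex as a covariate, 2216 (823 and 1393) without cKO MED1 replicates 3 and 4, and 1307 (513 and 794) at an adjusted p of 0.01. Lower calls numbered 4371 with total reads and 1624 with the stricter CPM filter, which tested 12562 genes, and higher calls 1286 with the neuronal and muscle level subtracted. Leaving out single libraries gave 1362 to 6278 calls, 521 to 3090 higher and 841 to 3188 lower, lowest without wild-type replicate 1. The totals were also below the main count by over 1.5 times without wild-type replicate 2 (2990) and cKO MED1 replicate 4 (2969). Higher calls alone moved that far without wild-type replicate 3 (1592) and cKO MED1 replicate 3 (1531). The smaller number of libraries does not account for all of these shifts, as 6278 calls were made without cKO MED1 replicate 1. Wild-type replicate 1 had the lowest satellite reads, at 147723 against 647105 and 657917 in wild-type replicates 2 and 3. Its reads of silent genes were the lowest as well. The cause of the shifts was not tested. In none of these fits did a shared call change direction. DESeq2 called 6137 genes, 4936 of them shared.

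The 7 libraries form 35 splits into 3 and 4, of which 1, the real one, gave as many calls: 5065 against 7 in the highest other, which is the split by sex. A share of 1 in 35 is the smallest this design allows, so chance is not excluded. The other splits mix the groups, which raises the spread and leaves few calls. They also cannot separate genotype from depth, sex or the reads of silent genes, which went largely with it. Same-numbered deviations correlated at 0.51, -0.23 and 0.16, which does not settle whether the replicate numbers pair the libraries. Wild-type replicate 1 correlated at 0.51 and 0.40 with cKO MED1 replicates 1 and 2, and at -0.26 and -0.58 with replicates 3 and 4. These values went with the reads of silent genes, whatever the number. The replicate block gave 3741 calls, with a genotype effect that rests on replicates 1 to 3 of each group.

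Camera called 9 lists, 0 with an estimated correlation and 8 to 13 with single libraries left out. Of the 9, fry called only the IgH constant list, and 8 were lost. Fry's 3 calls also held the marginal zone and megakaryocyte lists, which pointed higher and which camera had not called. The oxidative phosphorylation list was lost with sex as a covariate, and the super-enhancer and mature B cell lists without cKO MED1 replicates 3 and 4. Of the 139 named genes, 86 calls ended with the sex covariate and 87 with the surrogate variable, in which Ighe had adjusted p = 0.0281 and 0.0508. The Bax call ended in 8 alternatives. Kit, not called before (0.27), was called lower (-2.86) with the neuronal and muscle level subtracted, from means of 15.8 and 24.8 reads. The Ig share difference ranged from -0.770 percentage points without wild-type replicate 2 to -0.005 without wild-type replicate 3. Every wild-type library was deeper than every cKO MED1 library.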

Other observations

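The tests in this part were chosen after the result was seen.

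Of 125 Ighv segments tested, 50 were higher and 30 lower in cKO MED1 by limma's adjusted p, and of 107 Igkv segments 6 were higher and 10 lower. Near-identical V segments can share reads, so single segments are uncertain, and the difference between the loci was not tested. A sequence difference between strains was not tested either.

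Genes near Med1 on chromosome 11 were called with a fold of 2 or more at a higher rate than other autosomal genes with a mean of at least 100 normalised reads. Within 20 Mb of Med1, 21 of 385 genes (5.45%) were so called, against 199 of 10076 elsewhere (1.98%), a ratio of 2.76 (Fisher's exact p = 6.02e-05). The genes so called near Med1 include the Schlafen genes Slfn1, Slfn5 and Slfn8, all lower, and Cygb and BC018473, both higher. Fisher's test treats genes as independent, but some of these are neighbours, as the Schlafen genes start between 82951349 and 83116849. Its p may therefore be too small. Other causes for the changes of single genes in this region were not tested. One hypothesis is that a flanking segment of another strain came with the targeted allele, which may place part of the largest changes outside the effect of Med1. Regulation of neighbouring genes by Med1 was not tested and stays open.

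Cd79a fell by 0.88 on the log2 scale. The log2 ratio of Cd79a to Cd79b, its partner chain, was lower by 0.48, with every cKO MED1 library below every wild-type library (exact permutation p = 0.0286, the smallest the design allows). A hypothesis is that 1 Cd79a allele was interrupted, as by a Cre insertion, with a log2 fold change of -0.88 near that of a lost allele. The labels name no Cre line, and lower expression of Cd79a without such an insertion could give the same values.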
